A study of Mus musculus with 2 samples.

How the data were processed

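H3K4me3 was measured by chromatin immunoprecipitation and sequencing in liver of B6NCrl mouse embryos at embryonic day 13.5, pooled from males and females, per the labels. There were 2 biological replicates, which are separate biosamples, with DNA fragments of 300 to 500 bp, per the labels. The authors deposited 4 peak lists on mm10, per the README deposited with the samples: 1 list per replicate, 1 from the pooled reads and 1 of replicated peaks. Each replicate's list was derived from that replicate's alignments and 1 further file, the pooled list from both replicates' alignments and further files, and the replicated list from the pooled list and each replicate's list, per the same README. The peak caller, its version and threshold, the aligner and read depth were not given in the sources used here, so the precision that depth allows is unknown. Reads and alignments were not analysed here.

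The deposited lists are in narrowPeak format and hold, for each peak, its position, a signal value, a -log10 p and a -log10 q, as the authors' peak caller gave them. The lowest deposited -log10 q was 0.198 in replicate 1, 0.385 in replicate 2, 0.280 in the pooled list and 0.639 in the replicated list. The deposited signal values were used within a list only, by rank and median, and were not compared between lists except by rank correlation. Widths were computed from the deposited coordinates, which were turned into 1-based positions for printing.

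Promoters were taken from the GENCODE M21 annotation, on the same build: a protein-coding gene was called marked where a peak reached within 1 kb of the TSS of any of its transcripts. Peaks of a list were merged into domains across gaps of up to 1 kb. The width of a gene is that of the widest domain at its promoter, in the replicated list unless said otherwise. The signal of a marked gene is the highest of the pooled list's peaks at its promoter, or of a replicate's own peaks where that list is used. Pooled peaks left out of the replicated list can enter it, and their signal was at most 4.88. CpG observed/expected ratios and GC content were computed over the window around each TSS and their median taken per gene. Peaks on scaffolds outside the chromosomes were left out of all gene tests: 16 in replicate 1, 16 in replicate 2, 15 in the pooled list and 12 in the replicated list.

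Before the data were examined, the comparisons, 25 gene lists, alternatives and a rule for named genes were fixed. The lists were hepatoblast and fetal liver, adult hepatocyte metabolism, complement and coagulation, erythroid, globin, haem and iron, megakaryocyte, haematopoietic stem and progenitor, macrophage, granulocyte and mast cell, lymphoid, endothelial, stellate with mesenchyme and mesothelium, cholangiocyte, neural, skeletal and cardiac muscle, pancreas with gut and lung, germ cell, housekeeping, cell cycle, cholesterol synthesis, imprinted, sex-linked, Hox cluster and olfactory receptor genes. They were written from general knowledge of the genes, and 3 symbols (Ahsp, Amy2a and Xist) matched no protein-coding gene. The rule named the genes of the 20 widest domains, the 10 genes of highest signal, and in each list the 4 widest marked genes and the first 3 unmarked genes in list order, with all globin and sex-linked genes, and genes outside it are said to be so.

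Marked shares of lists were compared with all other protein-coding genes by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 25 lists and a threshold of 0.05. Median width and signal of a list's marked genes were placed as percentiles among 10000 random lists of as many marked genes, and percentiles of 2.5 or less and 97.5 or more were counted. A pair of lists was compared by permutation of list labels with 100000 resamples. Overlaps between lists and with promoters were compared with 100 circular shifts along each chromosome, whose smallest possible p is 0.0099. A peak counted as shared where it overlapped a peak of the other replicate by at least 1 bp. Near-identical copies of the 2 kb around each TSS were sought with minimap2 2.31, and a promoter counted as copied where another place aligned over at least 1000 bp at 98% identity or more. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

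The alternatives fixed in advance were peaks with a deposited -log10 q of at least 5, sharing by 50% of both peaks, TSS windows of 0 bp and 2.5 kb, the 5'-most TSS of each gene, the pooled list, each replicate's list alone, and merge gaps of 0 bp and 3 kb. GENCODE basic transcripts were added as an alternative after seeing the data.

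The scripts were tested on simulated data, in 20 simulated peak sets over 21938 genes. Each held 1 planted list of 25 genes, which were all set as marked and made 3 times as wide. All 20 planted lists were called for marked share and reached percentile 97.5 of width. Of 480 null lists, 0 were called and 20 (4.17%) fell outside the percentiles. Of 240 null pairs, 15 (6.25%) had a permutation p under the threshold.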

Results

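The study measured trimethylation of histone H3 at lysine 4 (H3K4me3), a chromatin mark of active and poised promoters, by chromatin immunoprecipitation and sequencing. The tissue was whole liver of B6NCrl mouse embryos at embryonic day 13.5, pooled from males and females, a stage at which the liver houses both hepatoblasts and blood formation. There was 1 group of 2 biological replicates, so no condition was compared with another. The deposited lists held 33672 peaks for replicate 1, 33590 for replicate 2, 36723 for the pooled reads and 26557 for the replicated set. Read depth was not given in the sources used here. All coordinates are 1-based positions on mm10 (GRCm38). The signal of a peak is the value the authors' peak caller gave it and is used here within a list only, and a domain is a run of replicated peaks joined across gaps of up to 1 kb. A domain can reach the promoters of several genes, and its width then counts for each. With no gap bridged, 60 of 139 widths of named genes fell by over 1.5 times.

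The first question was how far the replicates called the same regions. Of the peaks of replicate 1, 27953 (83.0%) overlapped a peak of replicate 2 by at least 1 bp, and 28565 peaks of replicate 2 (85.0%) overlapped a peak of replicate 1. Circular shifts of the peaks along each chromosome gave 2.83% and 2.84% on average, and none of the 100 shifts reached the observed shares (permutation by shifting, p = 0.0099 for each, the smallest this number of shifts can give). Promoters were closer still: 14450 protein-coding genes were marked in both replicates, 173 in replicate 1 alone and 179 in replicate 2 alone. Spearman's rho was taken across the 14439 genes marked in both replicates and also in the replicated list, so genes that failed the authors' filter are left out. It was 0.915 for signal and 0.949 for domain width. Across 31088 overlapping peak pairs rho was 0.717 for signal. These correlations run across genes or peaks, which are not independent replicates.

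Peaks seen in a single replicate were short, weak and mostly away from promoters. In replicate 1, 22.2% of the 5719 unshared peaks lay within 1 kb of a protein-coding transcription start site (TSS), against 59.7% of its shared peaks, and their median width was 232 bp against 988 bp. In replicate 2 the shares were 21.9% of 5025 unshared peaks and 59.1% of shared peaks, with median widths of 224 bp and 948 bp. Both differences passed Fisher's exact test (two-sided), with p-values below what double precision can hold. With a TSS window of 2.5 kb the difference in promoter share between unshared and shared peaks was -21.3 and -22.2 percentage points, against -37.5 and -37.2 with 1 kb. The authors' replicated list kept 72.3% of the pooled peaks, and each of its 26557 peaks was a pooled peak with unchanged coordinates. The 10166 pooled peaks left out had a median width of 234 bp against 1253 bp for those kept, and 21.3% of them lay at promoters against 60.1%.

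H3K4me3 lay mainly at promoters. Of the replicated peaks, 15957 (60.1%) reached within 1 kb of a protein-coding TSS, against a mean of 6.44% and a highest value of 7.21% over 100 circular shifts (permutation by shifting, p = 0.0099, the smallest possible). By summit position, 17.7% lay in introns and 15.7% between genes, and 4.54% lay within 1 kb of another annotated TSS. Median pooled signal was 36.4 at protein-coding TSSs and 4.11 in introns. In all, 14532 of 21938 protein-coding genes (66.2%) were marked, and the share was 66.7% ± 0.0193 in the replicates' own lists (SD, n = 2). Marked promoters were richer in CpG dinucleotides: the median CpG observed/expected ratio was 0.602 (quartiles 0.393 and 0.764) for marked genes and 0.174 (quartiles 0.112 and 0.270) for unmarked genes, and median GC content was 56.6% and 45.1%. The median domain at a marked gene spanned 2500 bp.

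The list of embryonic hepatocyte lineage genes was marked in full, while most genes of adult liver metabolism were unmarked. All 28 genes of the hepatoblast and fetal liver list carried H3K4me3 (100% in each replicate; adjusted p = 0.000162, Fisher's exact test). Its widest domains were those of the liver transcription factors Prox1 (8299 bp; 8396.5 ± 306 bp over the replicates, SD, n = 2), Onecut2 (7382 bp; 7388 ± 495 bp), Tbx3 (6479 bp; 6613 ± 356 bp) and Foxa3 (5809 bp; 5293.5 ± 211 bp). The Prox1 domain spanned chromosome 1 from 190167446 to 190175744, and 28.3% of it was intronic. Foxa3 shared its domain with Sympk. In contrast, 9 of 30 adult hepatocyte metabolism genes (30%) were marked, fewer than the 66.3% of other genes (adjusted p = 0.000366, Fisher's exact test). With the TSS base itself as the window, 16.7% of the adult list and 82.1% of the hepatoblast list were marked, and the hepatoblast call was lost (adjusted p = 0.0675, Fisher's exact test). Among the marked adult genes were Glul, which makes glutamine (3623 bp; 3930.5 ± 633 bp), Gys2, the liver glycogen synthase (2465 bp), Ass1, of the urea cycle (2181 bp), and Pah, which hydroxylates phenylalanine (2070 bp). The cytochrome P450 genes Cyp2e1, Cyp1a2 and Cyp3a11 were unmarked. The difference between both lists was 70 percentage points (Fisher's exact test, two-sided, p = 4.63e-09). Their promoters also differed in median CpG observed/expected ratio, 0.478 for the hepatoblast list and 0.228 for the adult list. Marked shares were not matched on this ratio, so stage and CpG content cannot be told apart here.

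Hepatoblast promoters combined wide domains with low signal. The list's median width was 3427 bp, at percentile 99.6 among 10000 random lists of as many marked genes, while its median pooled signal was 16.2, at percentile 0.04, against a median of 48.4 over all marked genes. Low signal was common among the lists, 17 of 25 of which lay at percentile 2.5 or below. Of its 28 genes, 18 were wider than the median marked gene and 1 had a signal above the median. Named outside the rule, after their values were seen, the genes of the secreted proteins albumin and alpha-fetoprotein fell at the low end: Alb had a domain of 1901 bp and a signal of 6.89, and Afp 1846 bp and 4.76. The complement and coagulation list, also made of secreted liver proteins, was marked at 20 of 29 genes (69.0%; adjusted p = 0.881, Fisher's exact test). Its widest domains were at Serpinc1 (3712 bp), Serpinf2 (3425 bp), F2, which encodes prothrombin (3386 bp), and Fgg, a fibrinogen chain (3022 bp), and C4b, C8b and C9 were unmarked. With the TSS base itself as the window, the complement and coagulation share was 37.9% (adjusted p = 0.0112, Fisher's exact test).

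Red cell genes carried some of the broadest H3K4me3 domains. Of 29 erythroid genes, 27 were marked (93.1%; adjusted p = 0.00313, Fisher's exact test), with a median width of 7927 bp, above all 10000 random lists, and 9 had domains of at least 10 kb. The widest domain of any protein-coding gene lay at Ank1, the gene of the red cell membrane protein ankyrin (chromosome 8, 23033018 to 23062428; 29411 bp; 28927 ± 308 bp, SD, n = 2), and 98.1% of it was intronic. With the 5'-most TSS alone, Ank1 had 1568 bp. With no gap bridged it had 7293 bp, less than the 11963 bp at Epb41, so its rank holds only with gaps bridged and all TSSs used. Nfe2, an erythroid transcription factor, shared a domain of 22120 bp with Hnrnpa1 and Cbx5 (22225 ± 24 bp). Epb41, of the membrane skeleton, had a domain of 20027 bp (19640.5 ± 450 bp), and Zfpm1, a cofactor of Gata1, one of 16932 bp (18237.5 ± 1948 bp). Median erythroid signal was 55.6, at percentile 84.3. Slc25a37, the mitochondrial iron importer, and Car1, a carbonic anhydrase, were unmarked.

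Haem and iron genes followed the erythroid list, with which they share 3 genes. Of 18 genes, 17 were marked (94.4%; adjusted p = 0.0219, Fisher's exact test), with a median width of 7535 bp, above all 10000 random lists, and a median signal of 66.4, at percentile 99.0. The widest domains belonged to the haem synthesis enzymes Fech (12989 bp; 12954 ± 62.2 bp, SD, n = 2), Hmbs (12032 bp; 11780.5 ± 316 bp, shared with H2afx), Cpox (10393 bp) and Alad (10100 bp). In the globin list, 4 of 8 genes were marked (adjusted p = 0.569, Fisher's exact test). With the TSS base as the window 25% were, fewer than other genes (adjusted p = 0.0443, Fisher's exact test), since Hba-a1 and Hba-a2 had no peak on the base itself. The definitive alpha-globin genes Hba-a1 and Hba-a2 lay in a single domain with Hbq1a and Hbq1b (chromosome 11, 32280517 to 32301970; 21454 bp; 22093 ± 363 bp, SD, n = 2), of which 84.2% was intergenic. The adult beta-globin genes Hbb-bt (7157 bp; 7633.5 ± 817 bp) and Hbb-bs (5275 bp; 4730 ± 683 bp) were marked. The embryonic globins Hba-x, Hbb-y, Hbb-bh1 and Hbb-bh2 had no replicated peak, and Hba-x had a peak in the replicate 1 and pooled lists alone.

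**Figure D1:**
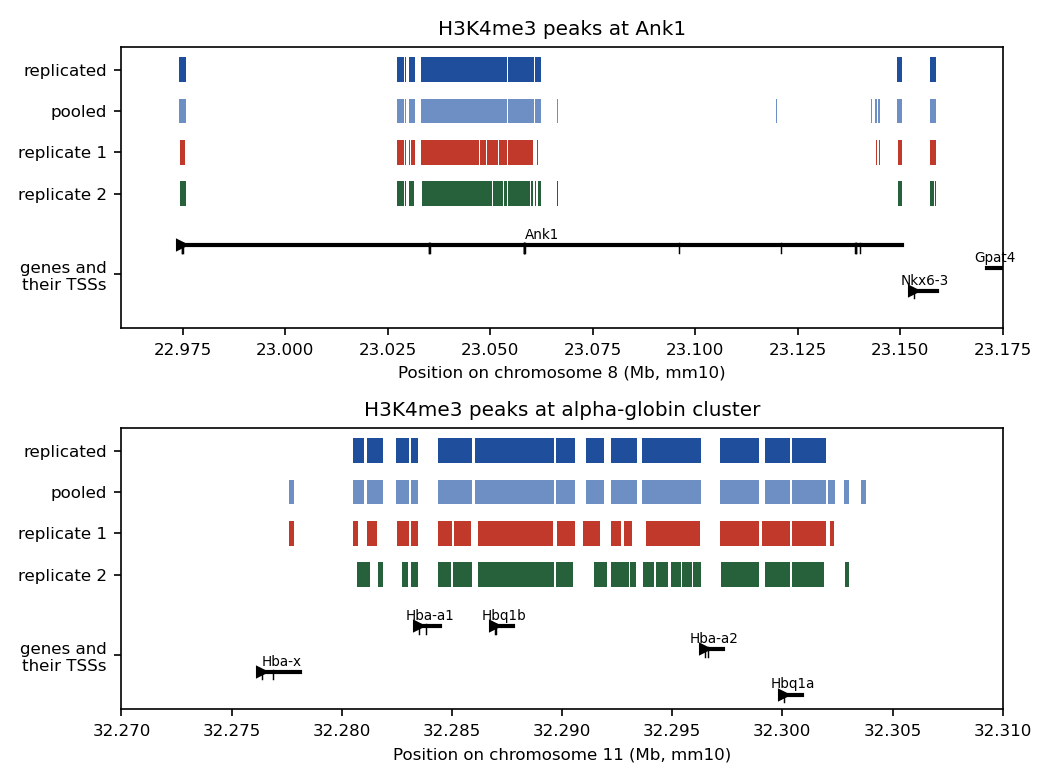
H3K4me3 peaks of the replicated, pooled, replicate 1 and replicate 2 lists (coloured blocks, 1 row per list) at Ank1 and at the alpha-globin cluster, by position in Mb on mm10; black bars are protein-coding genes, arrowheads their start and direction, and ticks annotated TSSs. The Ank1 domain of 29411 bp sits inside the gene around internal TSSs, and the globin domain of 21454 bp is a run of short peaks that begins downstream of Hba-x.

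The liver at this stage is both a hepatic and a blood-forming organ, and the gene lists of these lineages were compared directly. The erythroid median width was 4500 bp larger than that of the hepatoblast and fetal liver list, 2.31 times as large (permutation test over genes, two-sided, 100000 resamples, p = 1e-05, the smallest they can give). The erythroid median signal was also higher, by 39.4, or 3.43 times (permutation test, p = 1e-05, the smallest possible). Genes are not replicates, and these tests describe the lists in whole liver. Cell types were not separated and their shares not measured, so the values are not differences between cells of these lineages.

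**Figure D2:**
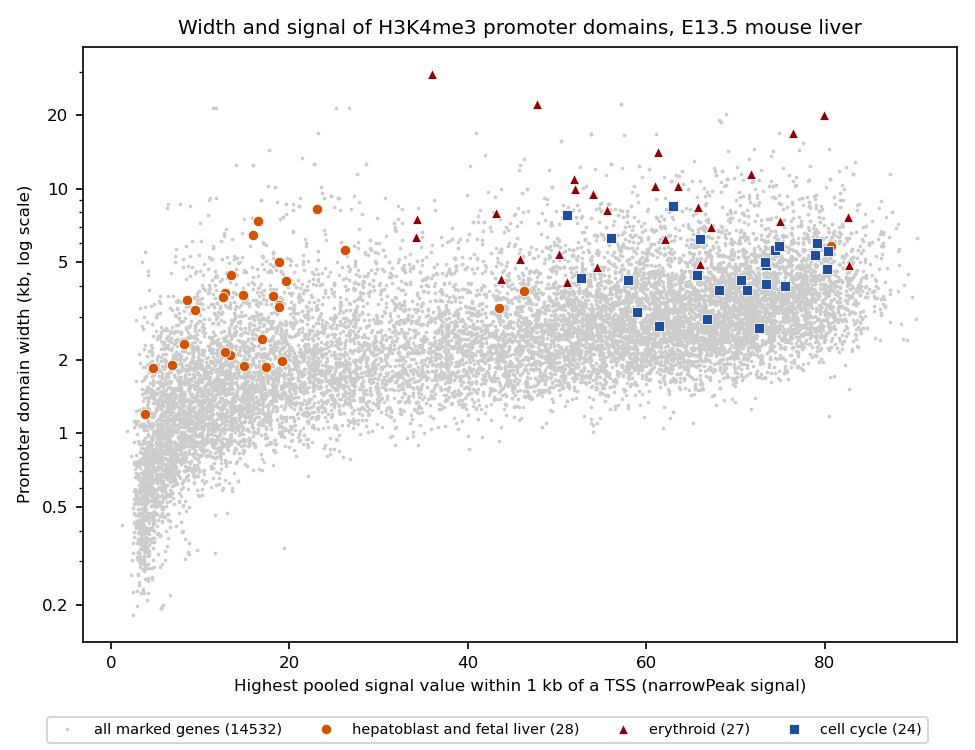
Each point is a marked protein-coding gene, by its highest pooled signal value within 1 kb of a TSS and its domain width in kb on a log scale; grey points are all 14532 marked genes and coloured symbols are members of the hepatoblast and fetal liver (28), erythroid (27) and cell cycle (24) lists. Hepatoblast genes lie mostly at low signal (median 16.2), erythroid genes at high width (median 7927 bp) and cell cycle genes at high signal (median 71.0).

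Other blood lineages differed widely. All 21 haematopoietic stem and progenitor genes were marked (adjusted p = 0.000929, Fisher's exact test), with a median width of 4923 bp, above all 10000 random lists, and a median signal of 19.3, at percentile 0.91. The transcription factors Lmo2 (16860 bp; 12672 ± 5644 bp, SD, n = 2), Runx1 (7718 bp; 7718 ± 89.1 bp, and 4895 bp with the 5'-most TSS), Lyl1 (7633 bp, shared with Nfix) and Meis1 (7627 bp) had the widest domains. Megakaryocyte genes were marked at 12 of 16 (adjusted p = 0.683, Fisher's exact test), led by Itga2b (3596 bp), Tubb1 (3322 bp; 2491 ± 1236 bp), Thbs1 (3037 bp) and Gp5 (3006 bp), and Gp6, Ppbp and Selp were unmarked. Macrophage genes were marked at 11 of 22 (adjusted p = 0.183, Fisher's exact test), with Mafb (4957 bp) and Irf8 (3292 bp) the widest and C1qa, Vsig4 and Clec4f unmarked. They were marked less often than other genes with peaks of -log10 q of at least 5 (31.8%, adjusted p = 0.00268) and with the TSS base as the window (22.7%, adjusted p = 0.000638), by Fisher's exact test. Granulocyte and mast cell genes (3 of 14; adjusted p = 0.00233) and lymphoid genes (10 of 24; adjusted p = 0.0285) were marked less often than other genes by Fisher's exact test. The lymphoid share was 25% with the 5'-most TSS alone and the granulocyte share 35.7% without replicate 2, both still lower. The marked granulocyte genes were Mpo, Prtn3 and Cebpe, and Elane, Ctsg and S100a8 were unmarked. Gata3 (8630 bp, and 1394 bp with the 5'-most TSS), Bcl11b (4166 bp), Lck (3123 bp) and Tcf7 (2600 bp) were the widest lymphoid domains, and Cd19, Cd79a and Igll1 were unmarked.

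Lists of the other liver cell types had no call of marked share in the replicated list. Endothelial genes were marked at 19 of 24 (adjusted p = 0.281), stellate, mesenchyme and mesothelium genes at 16 of 24 (adjusted p = 1) and cholangiocyte genes at 9 of 12 (adjusted p = 0.828), all by Fisher's exact test. In the pooled list the endothelial share was 91.7%, above that of other genes (adjusted p = 0.0250, Fisher's exact test). Gata4 (7607 bp, and 3683 bp with the 5'-most TSS) and Dll4 (6858 bp) were the widest endothelial domains, Foxf1 (8817 bp) and Lhx2 (7795 bp, and 1180 bp with the 5'-most TSS) the widest mesenchymal domains, and Sox4 (5039 bp) and Sox9 (4424 bp) the widest of the cholangiocyte list. Stab2, Lyve1 and Emcn of the endothelium, Col3a1, Lum and Msln of the mesenchyme, and Krt7, Spp1 and Cldn4 of the bile duct were unmarked.

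Genes of organs other than the liver were mostly unmarked, except neural genes. These lists also differed in median CpG observed/expected ratio: 0.255 for muscle, 0.332 for germ cell, 0.469 for pancreas, gut and lung, and 0.564 for neural genes. Marked shares were not matched on this ratio, so tissue and CpG content cannot be told apart here. Skeletal and cardiac muscle genes (4 of 21; adjusted p = 0.000154), germ cell genes (4 of 14; adjusted p = 0.0173) and pancreas, gut and lung genes (7 of 19; adjusted p = 0.0241) were marked less often than other genes by Fisher's exact test. The muscle regulators Myod1, Myf5 and Myog, the germ cell genes Ddx4, Prm1 and Prm2, and the pancreatic genes Ptf1a, Ins1 and Ins2 were unmarked. The widest domains in these lists belonged to Pax3 (1470 bp; 1141.5 ± 284 bp, SD, n = 2), Gdf9 (2772 bp) and Foxj1 (3016 bp). Gdf9 shared its domain with Uqcrq. With the TSS base as the window 4.76% of muscle genes were marked, and in the pooled list 28.6%. With basic transcripts, added after seeing the data, 14.3% of germ cell genes were marked. The call of the pancreas, gut and lung list was lost without replicate 2 (adjusted p = 0.0514) and with the 5'-most TSS alone (adjusted p = 0.0538), both by Fisher's exact test. Neural genes were marked at 19 of 24 (adjusted p = 0.281, Fisher's exact test), with a narrow median domain of 1285 bp, at percentile 0.01. Gfap (4742 bp), Pax6 (4260 bp), Mbp (3184 bp, and 5952 bp with gaps of 3 kb bridged) and Sox1 (2572 bp; 1647.5 ± 1115 bp, SD, n = 2) had its widest domains, and Gad1, Slc17a6 and Snap25 were unmarked. Of 1093 olfactory receptor genes, 3 were marked, namely Olfr94, Olfr1033 and Olfr56, whose domain was shared with Ifi47. The share of 0.274% was 0.457% without replicate 1 and 0.0915% with the 5'-most TSS alone. Hox cluster genes were marked at 29 of 39 (adjusted p = 0.413, Fisher's exact test), with a median width of 1444 bp, below all 10000 random lists. In the pooled list 84.6% were marked (adjusted p = 0.0392, Fisher's exact test). Hoxa1 (4052 bp), Hoxb2 (3312 bp), Hoxa2 (2784 bp) and Hoxb4 (2620 bp) were the widest, with Hoxa1 and Hoxa2 at 9001 bp and Hoxb4 at 9517 bp when gaps of 3 kb were bridged, and Hoxb1, Hoxb13 and Hoxb8 were unmarked.

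The lists of housekeeping, cell cycle and cholesterol synthesis genes were marked in full. All 24 housekeeping and all 24 cell cycle genes (adjusted p = 0.000391 each) and all 19 cholesterol synthesis genes (adjusted p = 0.00233) carried the mark, by Fisher's exact test. Cell cycle genes had a median width of 4561 bp and a median signal of 71.0, both above all 10000 random lists, with Pcna, the DNA polymerase clamp (8485 bp; 8617.5 ± 248 bp, SD, n = 2), and Rrm2, a ribonucleotide reductase subunit (7815 bp; 8611 ± 1472 bp), the widest. Housekeeping genes had a median width of 4231 bp, led by Tubb5 (9176 bp) and Rpl13a (8802 bp). Among cholesterol synthesis genes Pcsk9 (4560 bp), Sqle (4500 bp), Dhcr24 (4483 bp) and Hmgcr (4136 bp) were widest. Imprinted genes were marked at 16 of 18 (adjusted p = 0.0766, Fisher's exact test), led by Igf2 (7525 bp; 7606 ± 494 bp) and Grb10 (5753 bp), and Ndn and Rtl1 were unmarked. They were marked more often than other genes with windows of 0 bp (adjusted p = 0.0420) and 2.5 kb (94.4%, adjusted p = 0.0210), by Fisher's exact test. Of 10 sex-linked genes, 8 were marked (adjusted p = 0.608, Fisher's exact test): Ddx3x (4740 bp), Kdm6a (3875 bp, and 6108 bp in the pooled list), Kdm5c (3703 bp) and Eif2s3x (2702 bp) on the X chromosome, and Eif2s3y (2378 bp), Ddx3y (1909 bp), Uty (1739 bp, and 2864 bp in the pooled list) and Kdm5d (1191 bp) on the Y chromosome. Zfy1, whose promoter has a near-identical copy, and Sry were unmarked, and the noncoding gene Xist had a domain of 4113 bp (3959.5 ± 200 bp). Over all 25 lists, 7 were marked more often and 7 less often than other genes. None of these shares was matched on CpG content. The median CpG ratio was 0.120 for olfactory receptor, 0.178 for granulocyte and 0.263 for lymphoid genes, against 0.645 for cell cycle and 0.698 for housekeeping genes. Erythroid genes went the other way, with 93.1% marked at a ratio of 0.313.

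Unmarked here means without a peak in the replicated list. Of the genes named as unmarked, the complement gene C1qa had a short peak in each replicate's own list (207 bp and 348 bp). Car1, Hba-x, Ctsg, S100a8, Lyve1, Col3a1, Gad1 and Hoxb1 had a peak in the replicate 1 list but not in the replicate 2 list. Cldn4, Snap25 and Hoxb13 had a peak in the replicate 2 list but not in the replicate 1 list. The pooled list is left out of this count. It held a peak at Car1, at Hba-x and among the named endothelial genes, whose list was marked at 91.7% there against 79.2%. Pooled peaks at the other named genes are not listed here, and the Hox (84.6%) and muscle (28.6%) shares were also higher in that list.

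**Figure D3:**
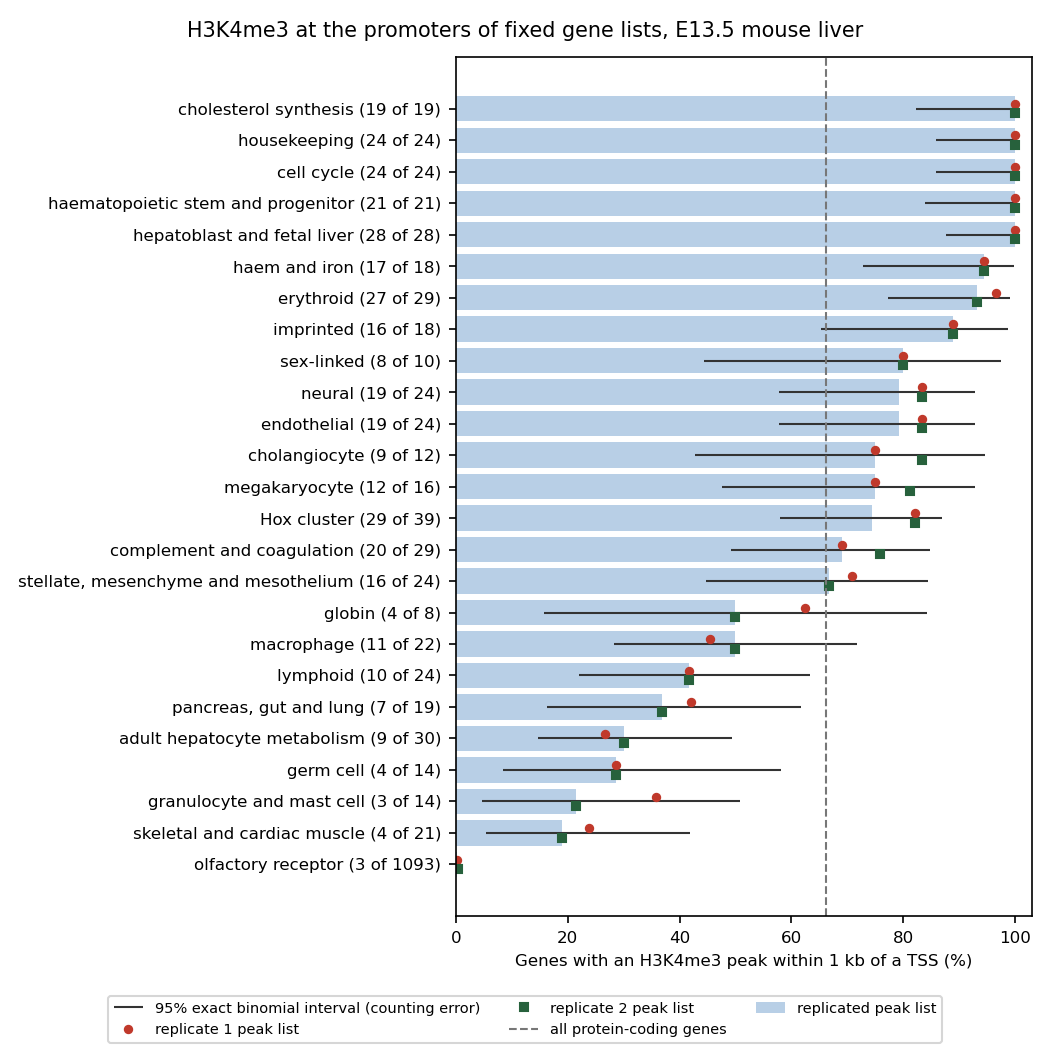
Share of each fixed gene list with an H3K4me3 peak within 1 kb of a TSS, in percent; bars are the replicated list, circles and squares the replicates' own lists, lines 95% exact binomial intervals and the dashed line all protein-coding genes (66.2%). Hepatoblast, progenitor, housekeeping, cell cycle and cholesterol synthesis lists reach 100%, and 3 of 1093 olfactory receptor genes are marked.

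Across the genome, 7 of the 20 widest promoter domains reached a gene of the erythroid, haem, globin or progenitor lists. After Ank1, Nfe2 and the alpha-globins came Rbm38 (20233 bp; 20213 ± 129 bp, SD, n = 2), Epb41, Tmcc2 (19168 bp; 14326 ± 6582 bp), Ranbp10 with Tsnaxip1 (18723 bp; 21394.5 ± 3672 bp), Zfpm1, Lmo2 and Hemgn with Trmo (16855 bp; 10445.5 ± 117 bp at Hemgn and 4179.5 ± 1238 bp at Trmo). The next were Junb with Prdx2, Rnaseh2a and Gm49661 (16796 bp), Zc3hav1 (16625 bp; 7478 ± 850 bp), Stradb with Trak2 (15608 bp), Gpr146 (15383 bp; 10899 ± 4311 bp), Bmp2k (14544 bp), Galnt10 (14516 bp), Setd1b with Rhof (14407 bp; 12940.5 ± 1966 bp at Setd1b and 8055 ± 8876 bp at Rhof), Gtpbp1 with Josd1 (14269 bp), Slc4a1, the red cell anion exchanger (14183 bp), and Ubac1 (13677 bp). With peaks of -log10 q of at least 5, widths were 10689 bp at Hemgn (470 bp with the 5'-most TSS), 3558 bp at Trmo, 5795 bp at Gpr146 and 8785 bp at Galnt10, and in the pooled list Stradb and Trak2 had 24031 bp. With no gap bridged, widths were 7293 bp at Ank1 and 1520 bp at Hba-a1. The highest signal belonged to Pabpc1 (90.4), Dnajc11 (90.2), Zbtb11 (89.8), Arf1 (89.4), Ipo11 (89.2), Trim33 (88.9), Sub1 (88.8), Psmd11 (88.5), Rock1 and Tcf3 (88.4 each), whose domains spanned 2417 to 6298 bp.

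Away from promoters, 4995 replicated peaks lay over 5 kb from any annotated TSS, with a median width of 628 bp and a median signal of 4.71, against 2111.5 bp and 39.4 for peaks that held a TSS. The widest distal domain was intergenic, at chromosome 19 from 12004455 to 12013675 (9221 bp; 9058.5 ± 91.2 bp, SD, n = 2), with Olfr1423 the nearest protein-coding gene. The next lay in an intron of the erythroid spectrin gene Sptb (chromosome 12, 76669473 to 76677585; 8113 bp; 6073 ± 2891 bp). The others were intergenic, near Dhx37 (chromosome 5, 125402696 to 125410357; 7662 bp), Hfe2 (chromosome 3, 96496585 to 96503589; 7005 bp) and Trim27 (chromosome 13, 21166713 to 21173705; 6993 bp).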

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

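In the replicated list, 12 H3K4me3 peaks lay on unplaced or unlocalized scaffolds, which no gene test here covered. Scaffold peaks were counted only in the overlaps between peak lists and among all peaks in the promoter share. The strongest spanned 2459 bp on an unlocalized scaffold of chromosome 4, with a signal of 53.5, and the next 1469 bp on an unlocalized scaffold of the X chromosome, with a signal of 36.0. No test was made of these peaks on their own.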

How the results depend on the processing

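In this part, only the tests with GENCODE basic transcripts were chosen after the results were seen. Of 94 alternative values for the main results, 18 moved beyond their spread. The other 76 kept direction and side of the threshold or, for counts of lists, stayed within 1.5 times: 13 to 17 lists were called for marked share, against 14, and 8 to 15 lay outside the width percentiles, against 11, not always the same lists. The erythroid domains stayed wider than the hepatoblast domains, by 3389.5 bp (merge gap of 0 bp) to 5943 bp (3 kb), and the hepatoblast share stayed above the adult hepatocyte share by 65.5 to 73.3 percentage points. Rank correlation of signal at shared peaks was 0.837 with peaks of -log10 q of at least 5 and 0.961 with sharing by 50% of both peaks, and the share of pooled peaks kept was 96.3% at that -log10 q. The share of genes marked was 65.8% at that -log10 q, 63.8% with a window of 0 bp, 67.1% with 2.5 kb, 62.6% with the 5'-most TSS, 67.8% with pooled peaks, 66.66% to 66.68% without a replicate and 65.3% with basic transcripts. The median CpG ratio of marked genes was 0.604, 0.612, 0.598, 0.722 and 0.595 under the first 5 of these, and 0.6005 to 0.6008 without a replicate. The 0.722 is another measure, computed at the 5'-most TSS alone, where the others took the median over the TSSs of a gene. The cause of the other moves was not tested.

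Of 250 list shares under alternatives, 8 gained a call, 3 lost it and 12 turned direction, with complement and coagulation genes at 0 bp both gaining a call and turning. The other calls were gained by macrophage genes (-log10 q and 0 bp), globin genes (0 bp), imprinted genes (0 bp and 2.5 kb), endothelial genes and Hox genes (pooled peaks), and lost by hepatoblast genes (0 bp) and by pancreas, gut and lung genes (5'-most TSS and without replicate 2). Complement and coagulation genes fell to 65.5% (-log10 q), 37.9% (0 bp) and 62.1% (5'-most TSS), megakaryocyte genes to 62.5% (-log10 q), cholangiocyte genes to 50% (0 bp) and Hox genes to 56.4% (0 bp and 5'-most TSS). Stellate genes turned at 62.5% (-log10 q and 5'-most TSS), 58.3% (0 bp), 66.7% (2.5 kb) and 66.7% (without replicate 1), but not without replicate 2 (70.8%). At 2.5 kb and without replicate 1 their share was that of the main setting. The share of all genes marked had risen past it, to 67.1% and 66.68%. The cause of the other changes was not tested. Of 139 widths of named genes, 60 moved by over 1.5 times when no gap was bridged, since their domains are runs of peaks, and 10 did so without replicate 1 and 10 without replicate 2. Median widths of the erythroid, haem and progenitor lists stayed above all random lists under all alternatives. Unknown read depth limits what the absence of a peak can show.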

Other observations

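Tests of gene families, of noncoding genes, of tRNA genes, of the Slc25a37 copy and of erythroid against hepatoblast signal were chosen only after results had been seen. Grouping protein-coding genes by the letters of their symbols gave 102 families of at least 20 genes, of which 51 were marked more often and 28 less often than other genes (Fisher's exact test, adjusted over families). Every gene was marked in the symbol groups Mrpl (49) and Mrps (29) of mitochondrial ribosomal proteins, Polr (28), Med (30) and Vps (35). This did not hold for the symbol groups Rpl (46 of 54), Rps (42 of 44), Atp (70 of 86) or Cox (23 of 27). Groups rest on letters alone, so a group need not hold only genes of a common function. Of 67 Hist genes, 60 were marked (Fisher's exact test, adjusted p = 3.46e-05), with a median width of 8531 bp, and 12 had domains of at least 10 kb. Neighbouring genes can share a domain, which then counts for each, and widths of families were not tested. Of 394 zinc finger genes named Zfp, 348 were marked. No gene was marked among the 57 hair keratin-associated Krtap genes, 42 beta-defensin Defb genes, 34 Scgb genes, 34 Rhox genes, 25 prolactin-related Prl genes and 22 major urinary protein Mup genes, and 27 of 100 Cyp genes were marked. Near-identical copies may limit the absences at 17 Mup, 16 Scgb, 14 Rhox, 2 Prl and 7 Cyp genes. Over all promoters, 48 of 1045 copied promoters were marked (4.59%) against 69.3% of others. These groups were not matched on CpG content or gene type, and 86 of the copied promoters belonged to Vmn genes. The gap therefore cannot show what copies did in these families. The Krtap and Defb genes had no such copy and no mark either.

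Of 5367 lincRNA genes with no protein-coding TSS within 2 kb, 471 (8.78%) were marked, with a median width of 1272 bp. Named after their values were seen, the nuclear RNA genes Malat1 (9788 bp; 10066.5 ± 885 bp, SD, n = 2) and Neat1 (9233 bp; 9449 ± 334 bp) had broad domains, and the imprinted H19 (3156 bp; 2873 ± 133 bp) and Meg3 (3152 bp; 3527.5 ± 709 bp) narrower domains. C230035I16Rik (9501 bp) and Gm11685 (8726 bp) were also among the widest.

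The iron importer gene Slc25a37, central to red cell haem synthesis, had no peak in any list, while 27 of 29 erythroid genes were marked. The 2 kb around its TSS had a second copy 218 kb away at 100% identity, with no peak at either copy, so reads that match both places may have been left out. Among genes with a CpG observed/expected ratio of at least 0.6, 30 of 69 with a copied promoter were marked (43.5%), against 7287 of 7415 others (98.3%), a difference of -54.8 percentage points (Fisher's exact test, p = 6.64e-48). The difference had been predicted for shared reads. These could explain missing peaks at 39 of the 167 CpG-rich unmarked genes, though 23 of the 39 had Gm or Rik symbols and may be unmarked for other reasons. The other 128 had no copy, the alpha-globin genes Hba-a1 and Hba-a2, each with a copy at 98.2% identity, had peaks within 1 kb of the TSS but none on the TSS base itself, and how reads with several matches were treated was not given in the sources used here.

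Hepatoblast promoters were wide and low in signal. Against random lists matched on CpG ratio the median signal of the list, 16.2, stood at percentile 0.17 (matched median 47.2), so promoter CpG content did not account for it. Erythroid genes, also tissue-restricted, had 3.43 times the hepatoblast median signal, so low signal was not shared by every such list. It was common, however: 17 of 25 lists had a median signal at percentile 2.5 or below, among them the endothelial (9.57), stellate (8.35), megakaryocyte (8.72) and progenitor (19.3) lists. Low signal at most tissue-restricted promoters therefore stays open as an explanation, and no biological explanation was tested.

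The breadth of erythroid and haem domains was not explained by merging or by signal. Over the 34 of these genes whose domain held a single protein-coding gene, the median width of 7781.5 bp stood at percentile 100 against such genes (matched median 2260.5 bp). Against lists matched on signal, 42 genes also stood at percentile 100 (7781.5 bp against 3024.5 bp). Broad domains at these genes may therefore be a feature of the lineage in this tissue, though no other tissue was compared and cell types were not separated.

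A pair of hypotheses on distal peaks was tested. Recognition words of GATA factors, which drive red cell genes, were in 23.8% of distal summits and 29.9% of flanks. A control word was in 19.6% and 26.0%. The summit-to-flank ratio of GATA words over that of the control word was 1.05 (95% resampling interval 0.975 to 1.15). GATA words were therefore not clearly enriched within 100 bp of the summits. The rest of each peak was not searched, so GATA sites there are not excluded. Of the 5 widest distal domains, 4 lay within 1 kb of tRNA genes, which the annotation used leaves out, against 0 in 100 circular shifts. Over all 4191 distal domains, 60 lay within 1 kb of a tRNA gene (1.43%), against a shifted mean of 0.0353% (permutation by shifting, p = 0.0099, the smallest possible), and their median width was 2133 bp against 703 bp for the others. Of the 50 widest, 7 did. The 60 domains are likely promoters of tRNA genes or their surroundings, and tRNA genes leave most wide distal domains unexplained.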
